A study of Mus musculus with 9 samples.

How the data were processed

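RNA of whole mouse kidney was sequenced in 9 libraries, 3 for each of 3 groups: wild-type sham, wild-type at day 14 after ischemia-reperfusion injury, and proximal tubular cell Pfkfb3 knockout at day 14 after the same injury. Per the labels, libraries were prepared from total RNA with a NEBNext Ultra RNA kit. The deposited values were counts of reads or fragments per Ensembl gene, not normalised, with 56305 gene identifiers and one column per library. The authors named the genome build mm10 and DESeq2 1.16.1, without saying what the latter was used for. The aligner, the counting tool, the annotation release and the use of strand are not given in the sources used here.

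Gene symbols and coordinates came from the GENCODE annotation of the same build, which matched 55141 identifiers and left 1164 unmatched. Library totals ran from 18707315 to 19987842 counts in sham, from 16946876 to 17873558 in injured wild-type and from 15626792 to 16426817 in injured knockout libraries. Groups were taken from the labels, and 0 sample columns were left unmapped. The replicate numbers of the labels were checked for pairing between groups and were not used as pairs.

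Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr kept 15974 genes, TMM scaled the libraries, and a quasi-likelihood model with one term per group was fitted to all 9 libraries. The 3 comparisons were 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a false discovery rate threshold of 0.05. CPM use TMM library sizes, and log2 CPM for principal components use a prior count of 2. Folds are those of the fitted model, and a group with no counts was set to a floor of 3 counts over the group, which covers counting error only. Genes moved back were those called with injury and called in the opposite direction between the injured groups. This count was set beside 10 simulations of unchanged groups and, added after the data were seen, 6 fits with the injured wild-type libraries split 1 against 2. With library size alone it was also set beside 10 simulations of libraries that differ in scale alone.

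Before the data were examined 40 gene lists were fixed. They were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 37 lists with at least 5 tested members, and again with the correlation estimated and with fry. The adrenal (1 of 8 members tested), skeletal muscle (4 of 11) and sex-linked (4 of 5) lists were not tested. A gene may be in several lists.

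The genes named were set by a rule written before the data were examined. The rule takes Pfkfb3 and, in each of the first 2 comparisons, the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups. It adds the 2 members with the smallest p in each of the 8 lists with the smallest p, and a fixed panel of injury, scar, NF-kB and metabolism genes. Of the panel, Il6 was removed by the low-count filter and has no value. Other names were added after their values were seen: genes behind a count of 5 or fewer, and genes singled out in the text.

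Alternatives changed one choice at a time: DESeq2 size factors in edgeR, library size alone, the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter, a mean CPM of at least 1, a fit to only the groups compared, library sizes without the 20 highest genes, a replicate block, a log2 fold change of at least 1, a false discovery rate under 0.01, and leaving out each library. A correction for GC content and transcript length was added after seeing the data.

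The procedure was tested on simulated data with the libraries' depth and spread, in which 400 genes changed over 2 separate runs in each comparison. With 3 libraries per group it recovered 15.7 to 17.9% of genes changed 1.5-fold, 55.2 to 58.2% of those changed 2-fold and 86.4 to 90.2% of those changed 4-fold, with 3.13 to 6.09% false calls. The threshold is less strict where more genes change, so these shares do not carry over to comparisons with many more changed genes.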

Results

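RNA was sequenced from whole kidney tissue of mice in 3 groups of 3 libraries each. The groups were wild-type littermates after a sham operation, wild-type littermates at day 14 after ischemia-reperfusion injury (IRI), and knockout mice at day 14 after the same injury. The injury was made by closing both renal arteries with a clamp for 30 minutes, a mouse model of acute kidney injury that is followed by inflammation and scarring. The knockout mice lacked Pfkfb3 conditionally in proximal tubular cells, the epithelial cells that reabsorb most of the filtered solutes. Pfkfb3 encodes an enzyme that sets the level of a strong activator of glycolysis. The design text names the part that PFKFB3 plays in kidney fibrosis as the question, and the title adds lactylation of histones and activation of NF-kB. Protein and lactylation were not analysed here, and neither was a knockout sham group. The labels do not say that the libraries of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical where libraries shared a mouse. Retrocopy transcripts that were abundant in some libraries of each injured group and nearly absent from others, given at the end, speak against one source for all 3 libraries of either injured group.

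The deposited values were counts per gene, and each library held from 15626792 to 19987842 counts. The 3 injured wild-type libraries stood apart from the other 6 on the first principal component, which held 69.7% of the variance of log2 CPM (counts scaled by library size). The second component held 10.2% and separated sham from injured knockout libraries. Across genes, sham and knockout libraries correlated at r = 0.964 to 0.976, against 0.877 to 0.908 for sham and injured wild-type libraries and 0.970 to 0.986 for libraries of one group. Genes are not independent replicates, so these values describe the libraries only. Transcripts encoded in the mitochondrial genome took 9.40% ± 1.61 of counts in sham, 6.45% ± 0.645 in injured wild-type and 13.2% ± 0.612 in injured knockout libraries (SD, n = 3). The 20 most abundant genes took 19.6% ± 2.01, 12.5% ± 0.0559 and 23.6% ± 0.507 of counts in the same order (SD, n = 3).

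**Figure D1:**
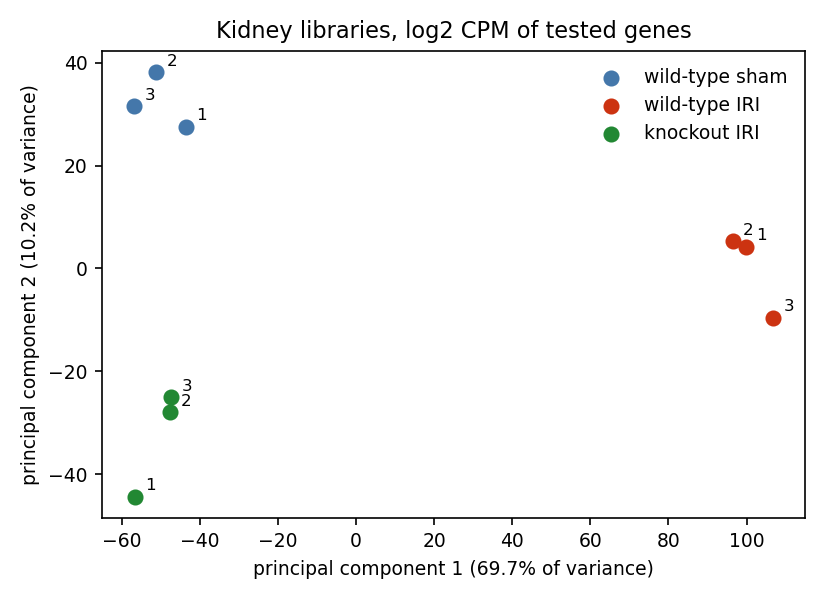
Principal components of log2 CPM over the 15974 tested genes, with one point per library, a color per group and the replicate number beside each point. The injured wild-type libraries lie at 96.4 to 107 on the first component and the other 6 libraries between -56.7 and -43.5.

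Pfkfb3 itself (ENSMUSG00000026773, protein-coding, chromosome 2, 11471433 to 11554077, mm10) was read first, since it is the targeted gene. Its level was 20.7 ± 1.06 CPM in sham, 32.0 ± 5.88 CPM in injured wild-type and 20.8 ± 4.04 CPM in injured knockout kidneys (SD, n = 3). Pfkfb3 rose 1.55-fold with injury in wild-type kidneys (log2 fold change 0.63, SE 0.17, adjusted p = 0.00685). It was 1.54-fold lower in injured knockout than in injured wild-type kidneys (log2 fold change -0.62, SE 0.17, adjusted p = 0.00773). Injured knockout and sham kidneys did not differ in Pfkfb3 (log2 fold change 0.01, SE 0.17, adjusted p = 0.988). Counts were summed over the whole gene and over all cell types of the kidney, so they check the genotype label only weakly, and the deleted part of the gene is not given in the sources used here.

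The first comparison asks what the injury changed in wild-type kidneys by day 14. Genes of scar tissue rose, and all 32 tested members of the list of fibrillar collagens and extracellular matrix were higher after injury. Col1a1, a chain of type I collagen, rose 44.2-fold from 15.3 ± 3.51 to 674 ± 106 CPM (SD, n = 3; ENSMUSG00000001506, chromosome 11, 94936224 to 94953042). Col3a1 rose 35.8-fold, fibronectin Fn1 11.2-fold, the collagenase Mmp2 19.2-fold and the collagen cross-linking enzyme Lox 15.7-fold. The smooth muscle actin Acta2, a marker of myofibroblasts, rose less, 1.64-fold to 96.8 ± 11.3 CPM (SD, n = 3). Of 23 members of the list of transforming growth factor beta (TGF-beta) signalling, 15 rose and 1, the inhibitory Smad7, fell (log2 fold change -0.68). Tgfb1 rose 3.49-fold and Ltbp2, also in this list, 56.9-fold (log2 fold change 5.83, and 6.60 without sham replicate 2). In the list of fibroblast, myofibroblast and pericyte markers 11 of 19 rose and 1, the smooth muscle myosin Myh11, fell (log2 fold change -1.12). In the list of basement membrane genes 10 of 16 rose and 2 fell. These 2, Col4a3 and Col4a4, encode chains of the type IV collagen of the glomerular filter and fell by 1.31 and 0.95 on the log2 scale. All 4 lists shifted upward by camera at its preset correlation, and none kept the call when the correlation was estimated (adjusted p = 0.0688 for matrix, 0.0835 for TGF-beta and for basement membrane, and 0.375 for fibroblast markers, with an estimated correlation).

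Transcripts of tubular injury rose and those of the working proximal tubule fell. RNA came from whole kidney, so changes within tubular cells and changes in the shares of cell types were not separated. Of 29 members of the list of tubular injury and failed repair, 27 rose. Havcr1, also known as kidney injury molecule 1, rose 126-fold from 2.91 ± 0.892 to 368 ± 87.9 CPM (SD, n = 3; ENSMUSG00000040405, chromosome 11, 46735080 to 46779578). Lcn2, which encodes a lipocalin used as an injury marker, rose 73.7-fold, and the keratin Krt20 rose 136-fold (log2 fold change 7.08, and 8.23 without sham replicate 2). The adhesion molecule Vcam1 rose 22.2-fold and Dcdc2a by 3.58 on the log2 scale, while the annexin Anxa2 rose 5.31-fold and Sema5a 2.26-fold. Of 24 markers of the first and middle proximal segments (S1 and S2), 23 fell, and all 13 markers of the last segment (S3) fell. The phosphate transporter Slc34a1 fell 4.07-fold from 6637 ± 498 to 1629 ± 467 CPM (SD, n = 3; ENSMUSG00000021490, chromosome 13, 55398187 to 55415592). The glucose transporter Slc5a2 was 3.55-fold lower, the endocytic receptor Cubn 4.61-fold lower, the organic anion transporter Slc22a8 5.34-fold lower and its relative Slc22a7 11.6-fold lower. Miox, the enzyme that breaks down inositol in the kidney cortex, was 3.83-fold lower. The adjusted p with an estimated correlation was 0.0688 for each of these 3 lists, which camera called at its preset correlation.

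Many genes of mitochondrial energy metabolism fell relative to the bulk of genes, although none of their lists was called with an estimated correlation. All 20 members of the tricarboxylic acid cycle list fell, as did 38 of 39 nuclear-encoded members of oxidative phosphorylation and 27 of 29 genes of fatty acid oxidation. The exception in oxidative phosphorylation was the ATP synthase subunit Atp5o (log2 fold change -0.49, adjusted p = 0.0501), whose sign turned with scaling by library size alone (0.07). Ehhadh, a peroxisomal enzyme of fatty acid oxidation, fell 7.83-fold, the electron carrier subunit Etfa 3.09-fold and the dehydrogenase Acads 3.41-fold. In the tricarboxylic acid cycle Suclg1 fell 3.67-fold, Idh3g 2.47-fold and Idh2 2.33-fold. In the respiratory chain Ndufs1 fell 2.82-fold, Uqcrc2 2.59-fold, Uqcrfs1 2.29-fold and Cyc1 2.26-fold. All 12 tested transcripts encoded in the mitochondrial genome fell, in step with the lower mitochondrial share of counts in these libraries. Of 12 members of the list of gluconeogenesis and fructose metabolism 11 fell, and 1, Pck2, rose (log2 fold change 0.69). Members of the list of NRF2 and ferroptosis fell in 12 of 16 cases and rose in 1, the cystine transporter subunit Slc7a11 (log2 fold change 2.20). Hypoxia targets fell in 10 of 15 cases. When libraries were scaled by size alone, the falls were 19 of 20 for the tricarboxylic acid cycle, 25 of 29 for fatty acid oxidation, 10 of 12 for gluconeogenesis, 8 of 12 for mitochondrial transcripts, 9 of 16 for NRF2 and 13 of 39 for oxidative phosphorylation. Hypoxia targets then fell in 4 cases and rose in 2, and their median moved from -0.59 to -0.05 on the log2 scale. With an estimated correlation the adjusted p was 0.0688 for fatty acid oxidation and hypoxia targets, 0.0835 for the tricarboxylic acid cycle, 0.152 for NRF2, 0.182 for gluconeogenesis, 0.240 for oxidative phosphorylation and 0.291 for mitochondrial transcripts.

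Glycolysis did not move as one group. Of 25 members of the list of glycolysis and lactate export 9 rose and 9 fell, and the list was not called (camera adjusted p = 0.977). Hexokinase Hk2, which starts glycolysis, rose 17.8-fold from 1.02 ± 0.224 to 18.3 ± 4.06 CPM (SD, n = 3). The neuronal enolase Eno2 and the lactate exporter Slc16a3 rose by 1.94 and 2.31 on the log2 scale. The more abundant Gapdh and Pgk1 fell by 0.87 and 1.09, and lactate dehydrogenase Ldha fell 1.57-fold from 893 ± 37.5 to 568 ± 35.9 CPM (SD, n = 3). The median of this list was 0.04 and its mean 0.34, while the test's direction was downward. When libraries were scaled by size alone, the median became 0.59 with 15 members up and 4 down, and Ldha no longer passed the test (log2 fold change -0.11).

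Immune transcripts rose broadly. Macrophage and monocyte markers rose in 23 of 25 cases. Lyz2, the lysozyme of myeloid cells, rose 26.1-fold from 31.1 ± 9.25 to 814 ± 58.2 CPM (SD, n = 3; ENSMUSG00000069516, chromosome 10, 117277331 to 117282321). The integrin Itgam rose 13.0-fold, the macrophage surface receptor Adgre1 9.89-fold and the receptor-like gene Fcrls 92.9-fold (log2 fold change 6.54, and 7.59 without sham replicate 2). Markers rose in 14 of 14 cases for dendritic cells and class II histocompatibility genes, in 18 of 19 for T and NK cells and in 10 of 10 for B and plasma cells. Complement genes rose in 15 of 17 cases, while C4a and Cfb fell by 1.84 and 3.48 on the log2 scale. C4a has a near-identical neighbour, C4b, with which it may share reads. Interferon-stimulated genes rose in 22 of 25 cases and cell cycle genes in 25 of 29. Among inflammatory cytokines and adhesion molecules 26 of 28 rose, with the chemokine Ccl2 up 54.6-fold, Cxcl16 5.93-fold, Tnf 41.6-fold (on 4 sham counts), Il1b 4.48-fold and the B cell growth factor Tnfsf13b 8.43-fold. The neutrophil attractant Cxcl5 lay at 17.9 ± 6.35 CPM in injured and at 0.0185 ± 0.0320 CPM in sham kidneys (SD, n = 3), too few counts in sham for a fold. The adjusted p with an estimated correlation was 0.0688 for macrophages, cytokines, complement and cell cycle, 0.182 for dendritic cells, 0.183 for T cells, 0.320 for interferon-stimulated genes and 0.337 for B cells.

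Genes of the NF-kB pathway, the transcription factor family named in the title, rose in 25 of 35 cases and fell in 4. Relb rose 5.20-fold from 9.98 ± 1.41 to 51.9 ± 15.3 CPM (SD, n = 3; ENSMUSG00000002983, chromosome 7, 19606217 to 19629438). Nfkb1 rose 2.53-fold, Rela 2.08-fold and the kinase subunit Ikbkb 1.28-fold. The 4 that fell were the kinase Chuk (log2 fold change -1.23), the kinase Irak1 (-0.83), the adaptor Traf6 (-0.42) and the kinase subunit Ikbkg (-0.27). With scaling by library size alone Traf6 no longer passed the test (0.12) and Ikbkg was higher after injury (0.27, adjusted p = 0.0446). Inflammasome genes rose in 9 of 13 cases and fell in 2, the sensor Nlrc4 (log2 fold change -1.09) and the kinase Nek7 (-0.60). The list of senescence and p53 targets held 10 of 14 rises and 3 falls, of Sesn2 (-2.40), the lysosomal galactosidase Glb1 (-1.10) and Ccng1 (-0.62). The adjusted p with an estimated correlation was 0.191 for NF-kB, 0.191 for the inflammasome and 0.152 for senescence. The call of Ikbkb (adjusted p = 0.0179) ended without sham replicate 3 or without injured wild-type replicate 2 (adjusted p = 0.0713 and 0.0778).

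The other lists were not called. In the list of histone acyltransferases and deacylases 3 of 17 members rose, Kat2a, Hdac2 and Hdac3 (log2 fold changes 0.26 to 0.36), and 5 fell. These were the mitochondrial deacylase Sirt3 (-1.92), Kat2b (-0.78), the alanyl-tRNA synthetases Aars (-0.63) and Aars2 (-0.42), and Sirt2 (-0.25). Not all members of this list are enzymes of histone marks. Over all 15974 tested genes 4708 rose and 4589 fell. In fits that left out a library the calls of Kat2a, Hdac3 and Hdac2 ended 6, 5 and 4 times. Those of Sirt2 and Aars2 ended 5 times and 1 time. With library-size scaling alone Sirt2 was higher after injury (0.29, adjusted p = 0.0101), the calls of Kat2b (-0.23), Aars (-0.09) and Aars2 (0.13) ended, and that of Sirt3 stayed (-1.38). Markers of the thick ascending limb fell in 6 of 12 cases and rose in 2, Cldn19 and Sostdc1 (log2 fold changes 1.04 and 0.85). Markers of the distal convoluted tubule fell in 6 of 11 cases and rose in 1, the magnesium channel Trpm6. Intercalated cell markers fell in 8 of 14 cases, and principal cell markers of the collecting duct in 4 of 11, the water channels Aqp3 and Aqp4, the sodium channel subunit Scnn1a and Tspan1. Podocyte markers fell in 1 of 12 cases, Clic5, and endothelial markers in 3 of 16, the receptors Kdr and Flt1 and the phosphatase Ptprb. Neutrophil markers rose in 4 of 8 cases, Cxcr2, Csf3r, Mmp9 and Il1r2, and fell in 1, Retnlg. Immediate early and heat shock genes rose in 4 of 15 cases, Junb, Egr3, Atf3 and Ier2, and fell in 1, Dusp1. The calls of Ier2 and Junb ended in 6 and 3 of the fits that left out a library. Adipocyte markers fell in 2 of 5 cases, Pck1, which the proximal tubule also expresses, and Thrsp. Of 6 erythrocyte markers 1, the anion exchanger Slc4a1, fell, which is also an intercalated cell marker. With scaling by library size alone the medians of the thick ascending limb, principal cell, intercalated cell, podocyte, endothelial, histone enzyme, adipocyte and erythrocyte lists turned from below to above 0.

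The 6 largest rises under the naming rule were Retnla, Cxcl5, the synaptic adhesion gene Lgi2 (285-fold), the ribonuclease Ear2 (140-fold), Krt20 and Havcr1. Retnla, a marker of alternatively activated macrophages, had no count in any sham library and was at least 263-fold higher after injury, against a floor of 3 counts per group. The 6 largest falls were the plasma glycoprotein Hrg (37.8-fold), Mpped1 (28.6-fold), the cytochromes Cyp2d12 (28.0-fold) and Cyp4a12a (25.2-fold), the BMP antagonist Chrdl1 (20.1-fold) and Sec14l3 (18.3-fold). Of these folds several rest on one library, and the log2 fold change was -6.83 rather than -5.24 for Hrg and -6.00 rather than -4.84 for Mpped1 without injured wild-type replicate 2. It was -6.18 rather than -4.81 for Cyp2d12 without replicate 1 and -5.24 rather than -4.33 for Chrdl1 without replicate 3. Lgi2 stood at 8.15 with all libraries and 9.68 without sham replicate 1, on 5 sham counts, and Ear2 rests on 6. Ear2, Cyp2d12, Cyp4a12a and Lyz2 have close paralogs and are uncertain where reads were shared. Cyp2d12, Itgam and Col3a1 overlap another gene on their own strand. Lox, Cubn, Anxa2, Ndufs1, Uqcrc2, Cxcl16, Fn1, Vcam1, Il1b, Slc5a2, Slc34a1 and Ltbp2 overlap a gene on the other strand, and no use of strand in counting is given in the sources used here.

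In all, 9297 of 15974 tested genes changed with injury by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4708 up and 4589 down, of which 2925 rose and 1870 fell at least 2-fold. Of 37 gene lists 25 shifted, 16 up and 9 down, and 0 did so with an estimated correlation, at a lowest adjusted p of 0.0688. Directions are relative to the bulk of genes: scaling by library size alone moved the median of all genes from 0.03 to 0.57 on the log2 scale, and 82.0% of 10868 calls were then up, against 50.6% of 9297. Adjusted over the list alone, counts differed in 8 lists, with 28 rises for tubular injury, 39 falls for oxidative phosphorylation, 26 rises for NF-kB, 11 rises for basement membrane and 9 falls for intercalated cells among them. Genes behind counts of 5 or fewer, and others outside the naming rule, were named after their values were seen. Of 54 changed genes named in this way for injury, 18 lost their call when some library was left out, and 19 lost it or turned their sign when libraries were scaled by size alone. The 19 were Aars, Aars2, Aqp3, Ccng1, Dusp1, Flt1, Ikbkg, Kat2b, Kdr, Nek7, Ptprb, Retnlg, Scnn1a, Sirt2, Slc4a1, Smad7, Thrsp, Traf6 and Tspan1.

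**Figure D2:**
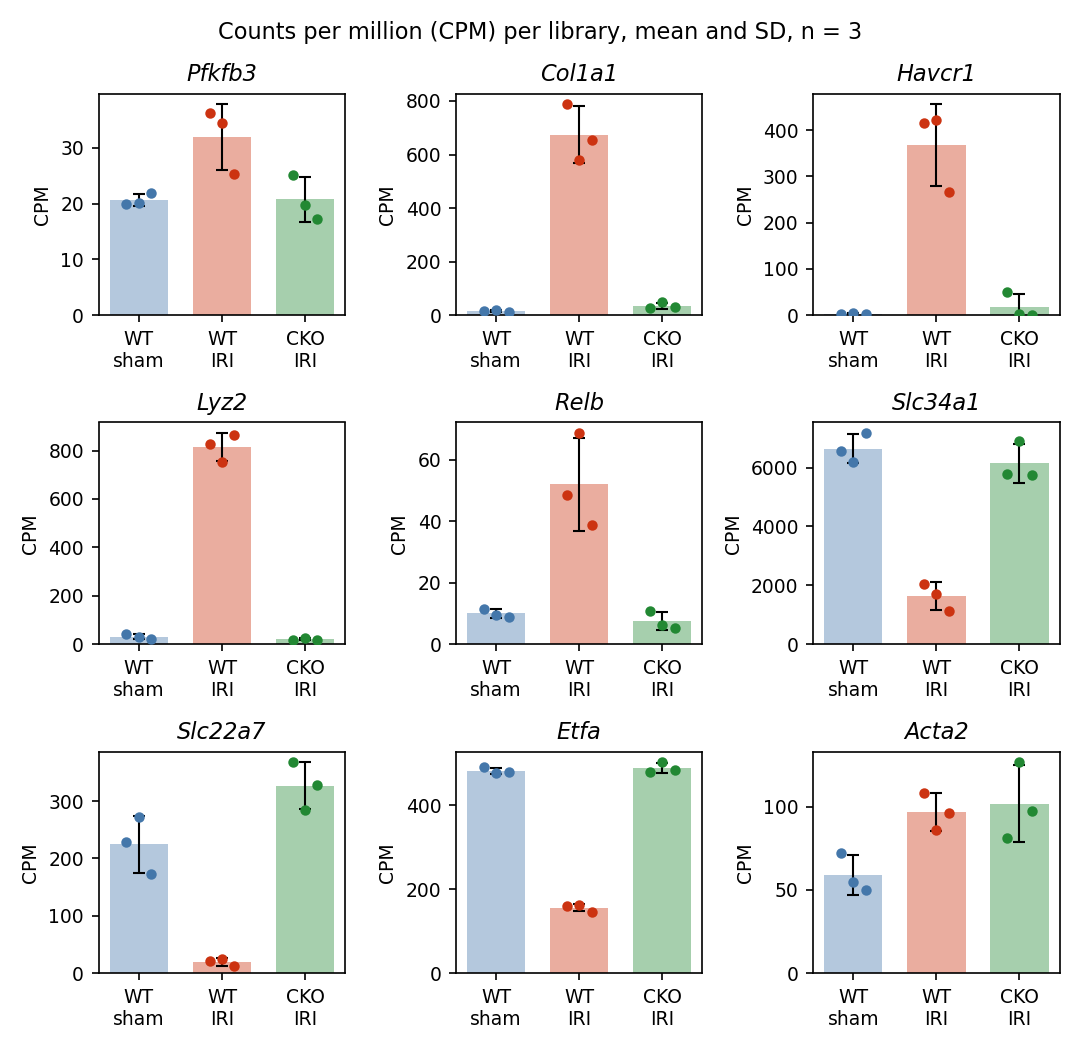
CPM of 9 genes in sham, injured wild-type and injured knockout kidneys, with bars for the mean, error bars for the SD (n = 3) and one point per library, on linear axes that start at 0. Col1a1 stands at 15.3, 674 and 34.3 CPM in the 3 groups, Slc34a1 at 6637, 1629 and 6140 CPM, and Acta2 at 58.9, 96.8 and 102 CPM.

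The second comparison, which the study's design is about, sets injured knockout kidneys against injured wild-type kidneys. Scar tissue genes were lower in the knockout: 31 of 32 members of the matrix list fell and 1, Col14a1, did not pass the test (log2 fold change -0.22, and 0.04 without knockout replicate 1). Col1a1 was 19.7-fold lower, at 34.3 ± 12.6 against 674 ± 106 CPM (SD, n = 3). Col3a1 was 19.5-fold lower, Fn1 7.19-fold, Mmp2 18.4-fold, Lox 13.4-fold and the fibril-associated collagen Col12a1 10.7-fold lower, as was Timp1, an inhibitor of matrix proteases (53.1-fold; log2 fold change -5.73, and -6.72 without knockout replicate 1). Acta2 was an exception, at 102 ± 23.1 CPM in knockout and 96.8 ± 11.3 CPM in wild-type kidneys (SD, n = 3; log2 fold change 0.07, SE 0.18, adjusted p = 0.749). With library-size scaling alone Acta2 was lower in the knockout (log2 fold change -0.51, adjusted p = 0.0186). TGF-beta signalling genes fell in 18 of 23 cases, with Tgfb1 4.42-fold and Ltbp2 63.6-fold lower (log2 fold change -5.99, and -6.60 without knockout replicate 1). Fibroblast, myofibroblast and pericyte markers fell in 9 of 19 cases and rose in 2, the smooth muscle genes Myh11 and Cnn1 (log2 fold changes 1.71 and 0.75). The call of Cnn1 ended in 3 fits that left out a library and with library-size scaling alone. Basement membrane genes fell in 11 of 16 cases and rose in 2, Col4a3 and Col4a4 (log2 fold changes 1.18 and 0.92). The call of Col4a4 ended when libraries were scaled by size alone. With an estimated correlation the adjusted p was 0.0801 for matrix, TGF-beta and basement membrane and 0.481 for fibroblast markers.

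Transcripts of tubular injury were lower and those of the proximal tubule higher in the knockout, again without a separation of cell shares. Tubular injury genes fell in 25 of 29 cases. Lcn2 was 31.2-fold lower, Vcam1 21.3-fold, Krt20 13.9-fold, Dcdc2a 11.3-fold, Anxa2 5.75-fold and Sema5a 3.48-fold lower, and Havcr1 fell by 4.32 on the log2 scale. Havcr1 differed between the knockout libraries, at 51.1, 3.17 and 0.963 CPM. Without knockout replicate 1 the log2 fold change was -7.49 rather than -4.32 for Havcr1, -6.64 rather than -4.96 for Lcn2 and -5.92 rather than -3.80 for Krt20. Markers of segments S1 and S2 rose in 22 of 24 cases and S3 markers in 12 of 13. Slc34a1 was 3.77-fold higher, at 6140 ± 652 against 1629 ± 467 CPM (SD, n = 3). Slc22a7 was 16.9-fold higher, Slc22a8 7.03-fold, Miox 5.40-fold, Cubn 3.10-fold and Slc5a2 2.39-fold higher. Slc5a2 varied between knockout libraries, from 78.1 to 227 CPM, and its call ended without knockout replicate 2 (adjusted p = 0.0665) and when libraries were scaled by size alone (adjusted p = 0.116). The adjusted p with an estimated correlation was 0.0824 for tubular injury, 0.107 for S1 and S2 and 0.0801 for S3.

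Mitochondrial energy genes were higher in the knockout. All 39 nuclear-encoded members of oxidative phosphorylation rose, as did all 20 of the tricarboxylic acid cycle, all 29 of fatty acid oxidation and all 12 transcripts encoded in the mitochondrial genome, in step with the higher mitochondrial share of counts in the knockout libraries. Ehhadh was 6.51-fold higher, Suclg1 4.26-fold, Acads 3.81-fold, Etfa 3.13-fold, Uqcrfs1 2.75-fold, Cyc1 2.71-fold, Idh2 2.66-fold, Idh3g 2.54-fold, Ndufs1 2.39-fold and Uqcrc2 2.12-fold higher. Genes of gluconeogenesis and fructose metabolism rose in 11 of 12 cases and those of NRF2 and ferroptosis in 11 of 16, while Slc7a11 fell by 3.51 on the log2 scale (4.20 without knockout replicate 1). Hypoxia targets rose in 8 of 15 cases. With scaling by library size alone the rises were 38 for oxidative phosphorylation, 18 for the tricarboxylic acid cycle, 25 for fatty acid oxidation, 11 for mitochondrial transcripts, 10 for gluconeogenesis and 7 for NRF2. Hypoxia targets then rose in 3 cases and fell in 5, and their median moved from 0.60 to 0.02. With an estimated correlation the adjusted p was 0.0801 for fatty acid oxidation, 0.107 for the tricarboxylic acid cycle and hypoxia targets, 0.117 for oxidative phosphorylation, mitochondrial transcripts and NRF2, and 0.149 for gluconeogenesis.

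Glycolysis again split, with 10 of 25 members up and 9 down in the knockout (camera adjusted p = 0.536). Hk2 was 15.5-fold lower, at 1.17 ± 0.498 against 18.3 ± 4.06 CPM (SD, n = 3), and Eno2 and Slc16a3 fell by 1.78 and 2.32 on the log2 scale. Ldha was 1.67-fold higher, and Gapdh and Pgk1 rose by 1.20 and 1.05 on the log2 scale. With library-size scaling alone 6 members were up and 16 down and the call of Ldha ended (log2 fold change 0.16). The median of this list was -0.01 and its mean -0.25, while the test's direction was upward. In the list of histone acyltransferases and deacylases 4 of 17 members rose, Sirt3 (log2 fold change 1.66), Aars2 (0.67), Sirt2 (0.34) and Kat2b (0.28). Another 4 fell, Ep300, Kat6a, Kat7 and Hdac2 (log2 fold changes -0.40 to -0.32). With library-size scaling alone Sirt2 and Kat2b were lower in the knockout (-0.24 and -0.30, adjusted p = 0.0264 and 0.0316). The calls of Kat2b, Kat7 and Kat6a ended in 5, 3 and 1 of the fits that left out a library. Immediate early and heat shock genes rose in 2 of 15 cases, Dusp1 and Dnajb1, and fell in 3, Junb, Egr3 and Atf3. The call of Junb ended in 6 of the fits that left out a library. Neither list was called (adjusted p = 0.719 and 1), and the median and mean lay on both sides of 0, at -0.06 and 0.07 for histone enzymes and at 0.18 and -0.19 for immediate early genes.

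Immune transcripts were lower in the knockout. Macrophage and monocyte markers fell in 24 of 25 cases, with Lyz2 39.6-fold lower at 20.6 ± 4.91 against 814 ± 58.2 CPM (SD, n = 3). Itgam was 20.1-fold, Adgre1 13.2-fold and Fcrls 57.3-fold lower. Falls were seen in 14 of 14 genes of dendritic cells and class II histocompatibility, 17 of 19 of T and NK cells, 10 of 10 of B and plasma cells, 7 of 8 of neutrophils and 25 of 25 interferon-stimulated genes. The neutrophil calprotectin subunit S100a8 fell by 3.32 on the log2 scale (4.45 without knockout replicate 1). Complement genes fell in 14 of 17 cases and rose in 2, C4a and Cfb (log2 fold changes 2.52 and 1.51), of which Cfb lost its call in 3 fits that left out a library and with library-size scaling alone (0.95, adjusted p = 0.131). Retnlg was also lower (-3.47, -5.66 without knockout replicate 1 and -2.18 and not called without injured wild-type replicate 3), on too few counts for a fold, and cell cycle genes fell in 22 of 29. Among cytokines and adhesion molecules 26 of 28 fell, with Tnf 33.8-fold, Ccl2 29.1-fold, Tnfsf13b 9.09-fold and Il1b 4.73-fold lower, while Cxcl16 fell by 2.58 on the log2 scale. Tnf rests on 4 knockout counts. The log2 fold change of Ccl2 was -7.55 rather than -4.87 without knockout replicate 1, and that of Il1b -2.91 rather than -2.24 without knockout replicate 3. With an estimated correlation the adjusted p was 0.0801 for macrophages, cytokines and complement, 0.117 for dendritic cells and cell cycle, 0.149 for T cells and neutrophils, 0.216 for B cells and 0.246 for interferon-stimulated genes.

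NF-kB pathway genes fell in 25 of 35 cases and rose in 2, Chuk (log2 fold change 0.96) and Irak1 (0.56). With library-size scaling alone Irak1 no longer differed (-0.02, adjusted p = 0.840). Relb was 6.97-fold lower at 7.46 ± 2.95 against 51.9 ± 15.3 CPM (SD, n = 3), Nfkb1 3.44-fold, Rela 1.96-fold and Ikbkb 1.30-fold lower. The call of Ikbkb (adjusted p = 0.0132) ended without injured wild-type replicate 2 and without knockout replicate 2 or 3 (adjusted p of 0.0604 to 0.0628). Inflammasome genes fell in 8 of 13 cases and rose in 1, Nlrc4 (0.58), which no longer differed with library-size scaling alone. Senescence and p53 targets fell in 7 of 14 cases and rose in 3, Sesn2, Glb1 and Ccng1 (log2 fold changes 1.40, 1.20 and 0.73). The adjusted p with an estimated correlation was 0.149 for NF-kB and the inflammasome and 0.132 for senescence. Distal tubule segments also held rises, in 10 of 14 markers of intercalated cells, 8 of 11 of the distal convoluted tubule, 9 of 11 of principal cells, and 7 of 12 of the thick ascending limb, where 1, Cldn19, fell (log2 fold change -0.51). Their adjusted p with an estimated correlation was 0.249, 0.315, 0.395 and 0.315. With library-size scaling alone the rises were 7, 4, 3 and 4 in the same order, and 1, 1, 1 and 3 members fell. Podocyte markers were not called, with 1 of 12 up, Clic5 (0.49, and -0.09 with library-size scaling alone), and 3 down, Synpo, Plce1 and Npnt. Endothelial markers passed the test in 0 of 16 cases by edgeR, and 12 were lower with library-size scaling alone. Adipocyte markers rose in 3 of 5 cases, Lipe, Pck1 and Thrsp, and erythrocyte markers in 1 of 6, Slc4a1, and neither list was called.

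The 6 largest falls under the naming rule were Retnla, Ear2 (134-fold), Cxcl5, Ltbp2, Fcrls and Timp1. Retnla lay at 0.0251 ± 0.0435 CPM in knockout and 15.3 ± 7.16 CPM in wild-type injured kidneys (SD, n = 3), and Cxcl5 at 0.219 ± 0.380 against 17.9 ± 6.35 CPM. Retnla had 1 knockout count, too few for a fold. Cxcl5 was 79.7-fold lower on 9 knockout counts and Ear2 rests on 5, all of them in knockout replicate 1. Lgi2 was 52.3-fold lower (log2 fold change -5.71, and -7.04 without knockout replicate 1). The 6 largest rises were Mpped1 (21.6-fold), Chrdl1 (18.6-fold), Cyp2d12 (18.4-fold), Slc22a7, Cyp4a12a (16.8-fold) and Hrg (16.4-fold), and Sec14l3 rose 12.7-fold. Without injured wild-type replicate 2 the log2 fold change was 5.59 rather than 4.43 for Mpped1 and 5.62 rather than 4.03 for Hrg, and without replicate 3 it was 5.13 rather than 4.22 for Chrdl1. Cyp2d12 (4.20) was at 5.57 without injured wild-type replicate 1 and at 3.51 without knockout replicate 2. By edgeR's quasi-likelihood test 8933 of 15974 genes differed, 4444 up and 4489 down in the knockout, of which 1869 rose and 2783 fell at least 2-fold. Of 37 lists 30 shifted, 13 up and 17 down, and 0 with an estimated correlation, at a lowest adjusted p of 0.0801. Scaling by library size alone moved the median of all genes from -0.01 to -0.59 on the log2 scale, and 16.9% of 10971 calls were then up, against 49.7% of 8933. Adjusted over the list alone, counts differed in 9 lists, among them 23 rises for S1 and S2, 13 for S3, 12 for NRF2 and 12 for intercalated cells, and falls of 19 for TGF-beta, 26 for NF-kB and 23 for cell cycle. Of 54 genes outside the naming rule that differed and were named after their values were seen, 12 lost their call when some library was left out and 14 lost it or turned their sign with library-size scaling alone. The 14 were Aars2, Ccng1, Cfb, Clic5, Cnn1, Col4a4, Dnajb1, Irak1, Kat2b, Lipe, Nlrc4, Sirt2, Slc4a1 and Thrsp.

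**Figure D3:**
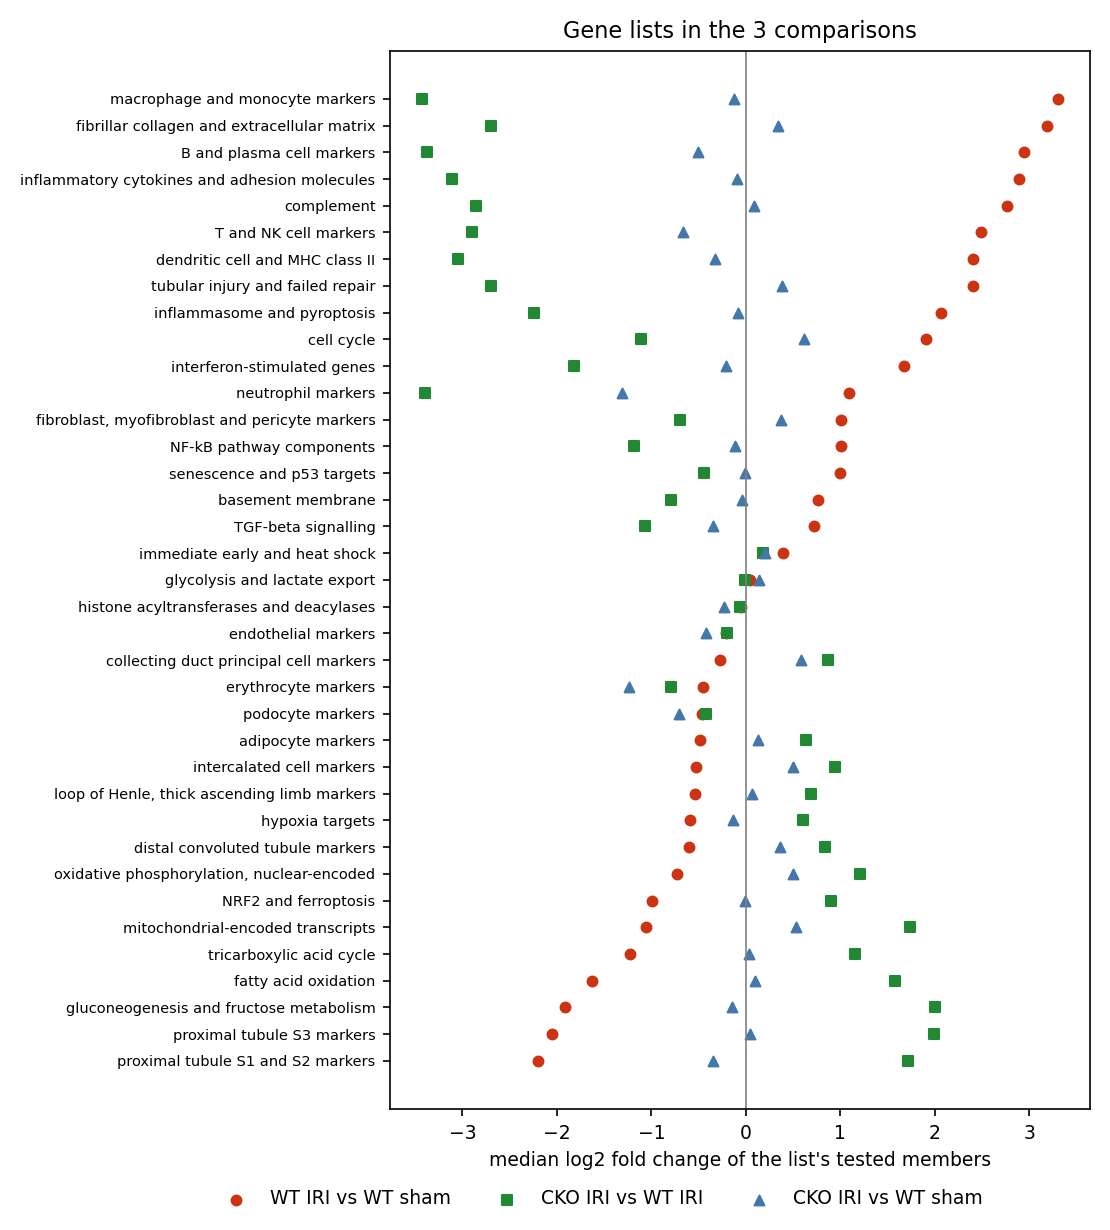
Median log2 fold change of the tested members of each of 37 gene lists, one row per list and one marker per comparison, on a linear axis with a line at 0. The matrix list lies at 3.19 for injury, -2.69 for knockout against injured wild-type and 0.34 for knockout against sham kidneys.

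The third comparison sets injured knockout kidneys against sham wild-type kidneys, so that injury and genotype differ together. Of the 59 named genes 9 differed. Matrix transcripts were partly above sham, with Col1a1 up by 1.17, Col3a1 by 0.88 and Fn1 by 0.64 on the log2 scale, while Col12a1 was down by 0.50. The smooth muscle actin Acta2, from the list of fibroblast, myofibroblast and pericyte markers, was up by 0.79. Of 32 matrix genes 6 were higher and 1 lower, and the list shifted upward at the preset correlation (camera adjusted p = 0.0105) but not with an estimated one (adjusted p = 0.897). The tubular gene Miox was higher (0.50), and Cubn (-0.57), Sema5a (-0.62) and Nfkb1 (-0.44) were lower. Leaving out one library ended the calls of Acta2 (sham replicate 2 or 3), Col3a1 (sham 1 or 3, knockout 2 or 3), Fn1 (sham 1 or 3, knockout 1 or 2) and Miox (sham 2 or 3, knockout 2 or 3). It also ended those of Col12a1 (any sham, injured wild-type 2, knockout 1 or 2) and Nfkb1 (any sham, injured wild-type 1, knockout 2 or 3), at adjusted p of 0.0512 to 0.137 over these 6 genes. The calls of Col1a1, Cubn and Sema5a passed with each library left out, but the GC content and length correction ended those of Cubn, Sema5a, Miox, Nfkb1 and Col12a1. Havcr1 and Krt20 lay above sham in mean but did not pass the test (log2 fold changes 2.65 and 3.28, adjusted p = 0.0914 and 0.0663), and without knockout replicate 1 they stood at -0.52 and 1.15. Krt20 stood at 4.41 without sham replicate 2 and did not pass. Both passed with no low-count filter, Havcr1 also without knockout replicate 3 and Krt20 without knockout replicate 2, and over all alternatives the adjusted p ran from 1.19e-09 to 0.627 for Havcr1 and to 0.526 for Krt20. Tubular injury genes were higher in 3 of 29 cases, the keratin Krt7 (0.74), the osteopontin gene Spp1 (0.90) and Plin2 (0.47), and lower in 1, Sema5a. The calls of Spp1 and Plin2 each ended in several of the 9 fits that left out a library.

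Oxidative phosphorylation stood above sham in the knockout, with 25 of 39 nuclear-encoded genes higher, a median of 0.50 on the log2 scale, and 4 of 12 mitochondrial transcripts higher, mt-Atp6, mt-Co2, mt-Nd3 and mt-Nd1 (log2 fold changes 0.62 to 0.82). All 4 calls ended without sham replicate 2 and without sham replicate 3. The share of mitochondrial transcripts was 13.2% ± 0.612 of counts in knockout and 9.40% ± 1.61 in sham libraries (SD, n = 3). After a correction for GC content and transcript length, chosen after seeing the data, 6 of 39 were higher and the median was 0.13. Cell cycle genes were higher in 10 of 29 cases, intercalated cell markers in 8 of 14, principal cell markers in 6 of 11 and distal convoluted tubule markers in 2 of 11, Trpm6 and Fxyd2. Neutrophil markers were lower in 4 of 8 cases, S100a8 (-2.73), S100a9 (-1.37), Cxcr2 (-2.52) and Retnlg (-5.47), the last with close to 0 counts in the knockout. Without knockout replicate 1 these were -3.86 for S100a8, -3.68 for Cxcr2 and -7.66 for Retnlg. Podocyte markers were lower in 3 of 12 cases, Magi2, Clic5 and Thsd7a, endothelial markers in 2 of 16, Flt1 and Ptprb, and TGF-beta genes in 5 of 23, Smad3 (-0.66), Smad4, Tgfbr2, Thbs1 and Skil. Markers of S1 and S2 were lower in 7 of 24 cases and higher in 1, Miox. These 11 lists and the matrix list were called at the preset correlation and 0 with an estimated one, at adjusted p of 0.684 to 0.897.

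The other 25 lists were not called against sham. Of all 15974 tested genes 1298 were higher and 1515 lower, 17.6% together, so a few called members do not set a list apart. Macrophage markers were higher in 3 of 25 cases, Lgals3, Gpnmb and Plac8, and lower in 1, Ccr2. Fatty acid oxidation genes were higher in 5 of 29 cases, Acaa2, Acaa1b, Eci1, Etfb and Cyp4a14, and lower in 2, Acadvl and the regulator Ppara (-1.63). NF-kB genes were higher in 2 of 35 cases, Tab1 and Tradd, and lower in 2, Nfkb1 and Tab2. Cytokine and adhesion genes were lower in 2 of 28 cases, Cx3cl1 and Icam1, and inflammasome genes higher in 1 of 13, Pycard, and lower in 3, Nlrp3, Casp4 and Nek7. Members of the list of histone acyltransferases and deacylases were higher in 1 of 17 cases, Hdac3, and lower in 4, Ep300, Kat2b, Kat6a and Aars. Senescence and p53 targets were higher in 3 of 14 cases, Cdkn2c, Bax and Phlda3, and lower in 2, Cdkn2b and Lmnb1. Hypoxia targets were higher in 1 of 15 cases, Higd1a, and lower in 3, Ndrg1, Ero1l and P4ha1, and NRF2 genes higher in 1 of 16, Gpx4, and lower in 2, Hmox1 and Gsr. Fibroblast markers were higher in 3 of 19 cases, Acta2, Myh11 and Cnn1, glycolysis genes in 2 of 25, Pfkm and Aldoa, gluconeogenesis genes in 1 of 12, Pck2, and interferon-stimulated genes in 1 of 25, Oas1a. Lower members were Atp11a and Slc16a9 for S3, Cfb and C5ar1 for complement, Pdha1 for the tricarboxylic acid cycle, Lamb1 for basement membrane and Ciita for dendritic cells. Of these genes Cdkn2b, Lmnb1, Ndrg1, P4ha1, Pdha1 and Slc16a9 kept their call with each library left out, and the others did not. Phlda3 lost its call in 9 such fits, and Acaa2, Gpnmb, Pfkm and Ero1l each in 8. By edgeR 0 members passed the test for T and NK cells, B and plasma cells, immediate early and heat shock genes, adipocytes and erythrocytes. Median, mean and test differed in sign for S3, complement, the tricarboxylic acid cycle, cytokines and NRF2, all with medians between -0.09 and 0.09.

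In this comparison 2813 of 15974 genes differed by edgeR's quasi-likelihood test, 1298 up and 1515 down, of which 222 rose and 218 fell at least 2-fold. The count rested on single libraries: it was 640 without sham replicate 2, 1064 without sham replicate 3, 1683 without knockout replicate 2 and 1560 without knockout replicate 3. It was 1425 after the correction for GC content and transcript length. Adjusted over the list alone, 30 genes of oxidative phosphorylation were higher and 1 lower, and 11 of 12 mitochondrial transcripts were higher. Of 84 genes outside the naming rule that differed from sham and were named after their values were seen, 68 lost their call when some library was left out.

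The comparisons were then set against each other gene by gene. Of 9297 genes that changed with injury, 7100 (76.4%) differed in the opposite direction between injured knockout and injured wild-type kidneys, and 38 in the same direction. Among them 3600 rose with injury and were lower in the knockout, and 3500 fell and were higher. Of the 59 named genes 58 were in this set, Acta2 being the exception. Many of these genes were named for large changes or small p in the same comparisons, so this share was set in part by the rule. Genes of it with the largest differences were Retnla, Ear2, Cxcl5, Ltbp2, Fcrls and Timp1 on the falling side and Mpped1, Chrdl1, Cyp2d12, Slc22a7, Cyp4a12a and Hrg on the rising side. Against sham kidneys, 7335 of the 9297 injury genes did not pass the test in the knockout, 1437 still differed in the direction of injury and 525 in the opposite one, in 2 comparisons that share the sham libraries. The last 2 counts were 359 and 91 without sham replicate 2, 554 and 168 without sham replicate 3, 933 and 290 without knockout replicate 2, 769 and 325 without knockout replicate 3, and 834 and 209 after the GC content and length correction. A gene that did not pass the test is not shown to be equal to sham. Among injury genes of at least 2-fold, a median of 9.63% of the log2 change remained in the knockout.

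Both comparisons use the injured wild-type libraries, so opposite chance values were built in. With independent lists 1323 genes would rise and then fall and 1277 fall and then rise. In 10 simulations of unchanged groups at most 1 gene was called in opposite directions, and fold changes correlated at -0.468 ± 0.0108 across genes (SD), against -0.887 observed. The covariance was -1.57 observed and -0.0442 simulated, a difference of -1.52. Neither value alone gives a shared effect. No gene changed in these simulations, so few calls in either comparison were built in. The simulations show only what shared chance error gives. When, in fits added after the data were seen, the injured wild-type libraries were split 1 against 2, so that the comparisons shared none, 5100 to 5737 genes moved back over 6 fits. The covariance was then -1.59 to -1.49 and the correlation -0.855 to -0.806. These fits remove the shared chance error of single libraries. A difference common to all injured wild-type libraries stays in both comparisons.

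**Figure D4:**
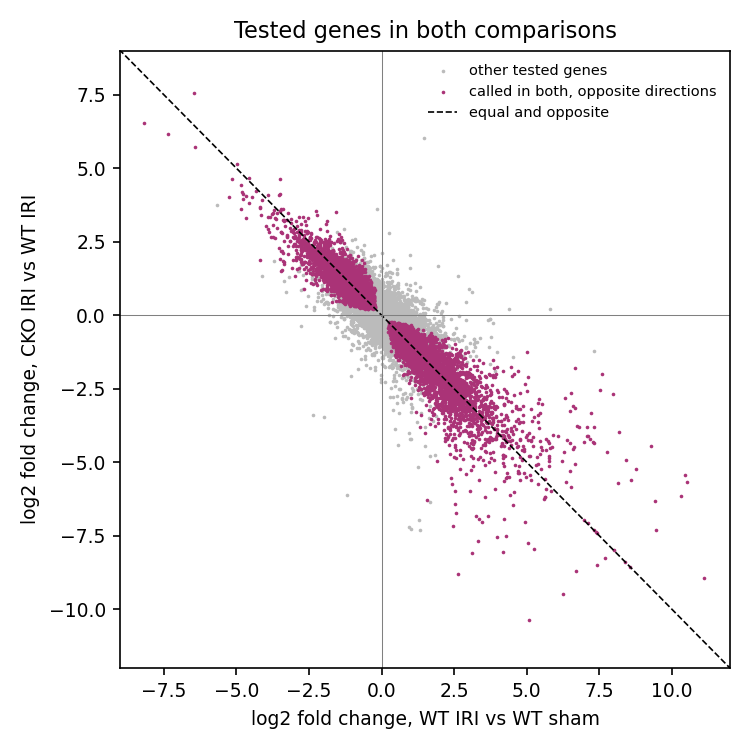
Log2 fold change of each of 15974 tested genes with injury (horizontal axis) and between injured knockout and injured wild-type kidneys (vertical axis), with a dashed line where both are equal and opposite. The 7100 genes called in both in opposite directions are colored, and over all genes the correlation was -0.887.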

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

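The alternatives were fixed before the data were examined, except the correction for GC content and transcript length, which was chosen after seeing the data. The injury comparison gave 9297 changed genes and from 8287 to 9865 when each library was left out, the comparison of the injured groups 8933 and from 7919 to 9057, and the comparison with sham 2813 and from 640 (without sham replicate 2) to 2868. Genes moved back were 7100 and from 6278 to 7060. DESeq2 and limma-voom gave 9327 and 9451 for injury, 8988 and 9000 for the injured groups, and 3590 and 2670 against sham. With a log2 fold change of at least 1 the counts were 4795, 4652 and 440, and 3632 genes moved back, since fewer genes can pass. At a false discovery rate under 0.01 the count against sham was 564, and with the GC content and length correction 1425. With library size alone 10868, 10971 and 2810 genes changed, of which 6661, 6341 and 2591 were shared with the reported calls. The replicate block gave 8885, 8527 and 2048 genes, and 6744 moved back.

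Pfkfb3 changed by 0.63 with injury (0.53 to 0.77 leaving out libraries) and by -0.62 between the injured groups (-0.78 to -0.50), both under the size limit of 1. Lists shifted were 25 for injury (25 to 28 leaving out libraries), 30 between the injured groups (28 to 30) and 12 against sham (10 to 16). With an estimated correlation they were 0, 0 and 0. The directional test of fry, which does not compare a list with other genes, gave 31, 31 and 5 in the same order.

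Of the genes under the naming rule besides Pfkfb3, 55 of 58 kept their direction and side of the threshold in every alternative run for injury and 53 of 58 between the injured groups. Against sham, with Pfkfb3 counted, 12 of 59 did. Among genes named after their values were seen, calls that ended or turned when some library was left out were 18 of 54, 12 of 54 and 68 of 84 in the 3 comparisons.

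Signs turned as follows on the log2 scale, and the cause was not tested except for library size alone, which moves the median of all genes by construction. With library size alone they were, for injury, Ikbkg 0.27, Traf6 0.12, Atp5o 0.067, Sirt2 0.29 and Aars2 0.13. Between the injured groups they were Acta2 -0.51, Irak1 -0.023, Nlrc4 -0.0048, Clic5 -0.090, Kat2b -0.30 and Sirt2 -0.24, and against sham Pfkfb3 -0.032 and Etfa -0.015. Against sham Pfkfb3 was also -0.016 with DESeq2 size factors, -0.016 with DESeq2, -0.013 with limma-voom, -0.013 with no filter and -0.016 with the replicate block. With limma-voom against sham Ear2 was -0.75, Vcam1 -0.040 and Ccl2 -0.22, and with the replicate block Ear2 was -0.012. With the GC content and length correction Acta2 was -0.18 between the injured groups. Against sham it gave Ear2 -0.17, Chrdl1 0.052, Mmp2 -0.11, Etfa -0.096, Idh3g -0.092, Tnfsf13b 0.085, Ikbkb 0.026, Rela -0.18, Ldha -0.094, Cyc1 -0.11, Acads -0.17 and Idh2 -0.099.

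Leaving out libraries turned signs between the injured groups for Acta2 (-0.11 to 0.22) and Col14a1 (-0.57 to 0.036). Against sham the ranges were Pfkfb3 -0.16 to 0.12, Retnla 0 to 2.69, Cxcl5 -1.94 to 4.99, Ear2 -4.18 to 0.65, Havcr1 -0.52 to 3.22, Chrdl1 -0.34 to 0.16, Mmp2 -0.19 to 0.30, Dcdc2a -0.26 to 0.26, Anxa2 -0.21 to 0.063 and Cxcl16 -0.061 to 0.047. They were Tnfsf13b -0.25 to 0.10, Lcn2 -0.44 to 1.72, Vcam1 -0.49 to 0.27, Ikbkb -0.15 to 0.045, Rela -0.046 to 0.18, Ccl2 -1.79 to 1.45, Tnf -0.23 to 0.69, Il1b -0.76 to 0.42, Hk2 -0.19 to 0.43, Ltbp2 -0.78 to 0.60 and Timp1 -1.34 to 0.18. With all libraries these genes, Acta2 and Col14a1 included, did not pass the test in the comparison in which they turned, and without knockout replicate 1 Ccl2 did pass it against sham (-1.79). Retnla ran from 0 (without knockout replicate 2) to 2.69 against sham and did not turn its sign. Depth limits genes near 0 counts in sham or knockout libraries, such as Retnla, Cxcl5 and Ear2.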

Other observations

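Tests chosen only after the result was seen were the GC content and length correction as an alternative, and the tests of library scaling, of missing injury or a wrong label, of a larger share of distal nephron cells, of mixed RNA, and of injured wild-type libraries split 1 against 2. Some genes in the injured knockout kidneys differed from both wild-type groups in one direction. There were 651 such genes, 353 higher and 298 lower, but 172 without sham replicate 2, 158 higher and 143 lower without sham replicate 3, 387 without knockout replicate 2, 395 without knockout replicate 3 and 315 after the GC content and length correction. Hprt, a purine salvage enzyme on the X chromosome, lay at 93.0 ± 9.05 CPM in sham, 99.5 ± 3.59 in injured wild-type and 30.1 ± 12.2 in injured knockout kidneys (SD, n = 3). The sulfotransferase Chst2 lay at 15.7, 16.1 and 6.10 CPM in the same order, and Myc, the interferon-inducible GTPases Tgtp1 and Iigp1 and the adhesion gene Vcl were also lower. Ciart, a repressor in the circadian clock, was higher by 2.05 and 1.78 on the log2 scale than in injured wild-type and sham kidneys, the protease Pcsk4 lay at 5.34, 5.73 and 14.5 CPM, and Cyp4a14, G0s2, Plk3 and S100g were also higher. Against sham the calls of Myc, Iigp1, Vcl, Cyp4a14, G0s2 and S100g ended when some library was left out, and those of Hprt, Chst2, Tgtp1, Ciart, Pcsk4 and Plk3 did not. A knockout sham group was not analysed here, so genotype and injury are not separated for these genes, and no cause was tested.

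Some libraries held transcripts that were lower or nearly absent in others of their group. The retrocopy Rps3a3 lay at 117 CPM in knockout replicate 1 and under 1 CPM in the other 8 libraries. Gm8730 lay at 98.5 CPM in injured wild-type replicate 1 and 114 CPM in knockout replicate 2, and Rps13-ps1 at 11.6 to 16.7 CPM in replicates 2 and 3 of both injured groups. No sham library held these transcripts at such levels, and the cause was not tested. In knockout replicate 1 Havcr1 lay at 51.1 CPM, Krt20 at 11.6 CPM, Lcn2 at 14.1 CPM and Spp1 at 1038 CPM.

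The first pattern is that injured knockout kidneys lay close to sham kidneys, with 7100 genes moved back. Scaling of the libraries as the only cause is argued against for the genes that fell and then rose. Size alone moved the median of all genes up with injury and down in the knockout, and 1330 genes still fell and then rose. In 10 simulations where libraries differed in scale alone at most 2 did. No gene changed in these simulations and their shift runs against such genes, so a low count was built in. With no library shared 884 to 1084 genes fell and then rose, against 127 to 168 with independent lists. How much of the closeness to sham came from scaling is not shown by these counts. The total of 9029 genes moved back in this setting decides nothing, since the shift adds opposite calls by construction. Knockout kidneys that were not injured, or libraries with a wrong label, stay open: 11 members of the tubular injury and matrix lists differed from sham, 9 of them upward, and at the preset correlation the matrix list lay above sham (camera adjusted p = 0.0105, and 0.897 with an estimated correlation) and the tubular injury list was not called (0.121 and 0.897), while without a knockout sham group an effect of genotype on these genes is not separated from injury. The knockout libraries also differed. Havcr1 lay at 51.1, 3.17 and 0.963 CPM in knockout replicates 1, 2 and 3 and at 2.32 to 3.93 CPM in sham libraries. Col1a1 lay above sham in each, at 25.5 to 48.7 CPM against 11.5 to 18.4 CPM. A milder injury in these animals, a smaller response in the knockout and a wrong label could not be told apart with these 9 libraries, and an effect of the knockout itself may also contribute, which was not tested apart from injury.

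The second pattern is that nuclear-encoded oxidative phosphorylation genes lay above sham in injured knockout kidneys, at a median of 0.50 on the log2 scale. After a correction for GC content and transcript length the median was 0.13 (SE over members 0.0387) and 6 rather than 25 of 39 members passed the test, so GC content and length may account for most of it. A remainder stayed, with a camera adjusted p of 0.00100 at the preset correlation (before the correction the list was not called with an estimated correlation, adjusted p = 0.781) and a median of 0.39 rather than 0.53 for mitochondrial transcripts, and these genes are short, so the correction could also remove real change. A larger share of distal nephron cells stays open, since the medians of the 4 distal lists ran from 0.062 (SE 0.143) for the thick ascending limb to 0.59 (SE 0.175) for principal cells. A biological difference between the groups was not tested apart from these.

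The third pattern is the tubular injury transcripts of knockout replicate 1, which also held Ccl2 at 5.77 CPM, against 0.377 and 0.275 CPM in the other 2 knockout libraries, and all knockout counts of Cxcl5 (9) and Ear2 (5). RNA of an injured wild-type kidney mixed into this library would bring matrix and macrophage transcripts too. The tubular injury list needed a median share of 6.69% (SE 3.86, 23 members). The matrix and macrophage lists needed -3.41% (SE 1.55, 51 members) and the cytokine list -0.324% (SE 3.64, 20 members). The matrix and macrophage lists thus gave no sign of mixing, while Ccl2, Cxcl5 and Ear2 go with it. These SE take the members of a list as replicates, which they are not. A negative share places replicate 1 below the mean of the other 2 knockout libraries, so its level without mixing is not known. Mixing is therefore not excluded. The test kept only members with at least 5 CPM in injured wild-type kidneys and at least 2 times the mean of knockout replicates 2 and 3. Stronger tubular injury in this sample may explain the pattern, which was not tested.

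Other splits of the libraries were counted. Each comparison of 6 libraries allows 10 splits, too few for a share under 0.05. The real split gave 9297 genes for injury, 8933 between the injured groups and 2813 against sham, reached by 1 split each, and the highest other split gave 0 genes in each. Lists behaved otherwise: 25 were shifted for injury, and 5 of the 10 splits shifted as many (highest other 27). Between the injured groups 30 were shifted, with 3 splits as high (highest other 31), and against sham 12, with 9 splits as high (highest other 22). Splits that mix the groups still hold part of the difference between them. Of 840 splits of the 9 libraries 60 were drawn for genes moved back, with the real one included by design. Only 1, the real one, gave as many as 7100, with 6565 as the highest other. The 2 other drawn splits that kept the injured wild-type libraries together gave 6565 and 6546, so the count shows that these libraries stood apart and says little on the labels of sham and knockout libraries. With only 2 such splits drawn, a random split of the sham and knockout libraries is not excluded as the source of the count.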
